A study of Mus musculus with 9 samples.

How the data were processed

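Kidneys of C57BL/6 mice were digested with collagenase, and the cells were cross-linked with disuccinimidyl glutarate and formaldehyde, sonicated and immunoprecipitated, per the labels' protocols. In the reChIP, chromatin recovered with the HNF1β antibody was precipitated again with an ERRγ antibody or with IgG, per the labels. The groups were input (3 libraries), ERRγ ChIP (2), HNF1β ChIP (2), HNF1β then ERRγ reChIP (1) and HNF1β then IgG reChIP (1), each taken from the labels, which also name the chromatin set. Whether the replicate libraries came from separate animals is not given in the sources used here. Input and IgG libraries had no values of their own in the peak lists and entered only through the authors' peak calls.

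Bowtie 1.2 and HOMER, and the builds mm9 and mm10, are named without roles, per the submitters' processing notes. The peak lists were annotated with HOMER's annotatePeaks.pl against mm10, per the file headers, and all coordinates are given on mm10 as the files give them. The ERRγ and HNF1β lists were merged from per-library lists called at a false discovery rate of 0.01, per the file headers, and every peak names both libraries of its factor. The reChIP list was merged from calls of the same library against the IgG reChIP, at 2-fold and a Poisson setting of 3, and against input, per the names in the file. Peak widths ran from 200 to 562 bp for ERRγ, 200 to 564 bp for HNF1β and were 200 bp for each reChIP peak.

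Each peak has 1 deposited peak score, a value of the authors whose scale is not given in the sources used here. Scores ran from 5.00 to 205 for ERRγ, 4.47 to 118 for HNF1β and 77.2 to 636 for the reChIP, and were not compared across lists. Every reChIP score was within 0.1 of a whole multiple of a step of 1.09, the best-fitting step near the smallest gaps between scores, and the lowest score was 71 steps. The ERRγ and HNF1β scores, 1 value for each pair of libraries, gave no such depth, so the depth of those libraries is unknown. The other columns used were start, end, distance to the nearest TSS, annotation and nearest gene, all as deposited.

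Peaks were compared by overlap of at least 1 bp. The overlap expected by position was taken from 1000 draws that moved every peak of 1 list by 20 to 200 kb up or down its chromosome. A gene was near a peak when the peak's nearest TSS, per the deposited annotation, was that gene's and lay within 10 kb. A promoter peak was centred within 1 kb of the TSS. The background of the gene list tests was the 21027 nuclear protein-coding genes with a curated (NM) transcript in the RefSeq table for GRCm38.p6, matched by Entrez identifier. This is a narrower reading of the planned background of protein-coding genes, made after the files were read, because annotation is by transcript and 0 genes near peaks lacked such a transcript. All 21883 protein-coding genes were run as an alternative. The 24 gene lists were fixed before the data were examined: OXPHOS complex I, complexes II to IV, complex V, TCA cycle, fatty acid oxidation, mitochondrial dynamics, mitochondrial ribosome, glycolysis, cytosolic ribosome, proteasome, proximal tubule, thick ascending limb, distal convoluted tubule, principal cell, intercalated cell, podocyte, endothelium, fibroblast, leukocyte, synapse, muscle, cystic disease, tubulopathy, and ERR and HNF1 factors.

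List members were compared with other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 72 tests. The ERRγ and HNF1β lists were compared by an exact McNemar test and by Fisher's exact test of the split of genes near 1 factor only, adjusted over 24 lists. Shares of HNF1β peaks with a reChIP peak were compared by Fisher's exact test and by a Mantel-Haenszel odds ratio over 5 groups of peak score. Promoter shares were compared by Fisher's exact test over 7 comparisons, and median log2 scores by a permutation test with 100000 permutations. Shares have 95% Wilson intervals, or exact binomial ones where stated, which cover counting error only. Odds ratios of gene lists have exact conditional intervals, and those of peak counts have intervals from the standard error of the log odds ratio.

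The genes named were set by a rule fixed before the data were examined. It takes Esrrg, Esrra, Hnf1b, Hnf1a, Hnf4a and Ppargc1a in each case, up to 4 members with the highest-scoring peak of each list that passed, the 10 protein-coding genes with the highest-scoring peak within 10 kb in each peak list, and the 10 with the highest-scoring reChIP peak on both an ERRγ and an HNF1β peak. Gene symbols are those of the RefSeq table.

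The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data. Of 600 overlaps planted between ERRγ peaks and moved HNF1β peaks in 1 simulation, 585 were found above the mean of the draws. In 50 simulations over 21027 genes at the ERRγ share, 88.8% of lists simulated at an odds ratio of 5 passed, and 1.65% of unchanged lists did. For the split of ERRγ against HNF1β, 23.2% of such lists passed and 0% of unchanged lists did, so this test misses many differences of that size. With the ERRγ peak made more common at high HNF1β scores over 12773 peaks, a true odds ratio of 1 gave 0.950 with score groups and 1.54 without, and a true odds ratio of 3 gave 3.07 and 4.30. Each true odds ratio was simulated only 1 time, so these values have no spread. Both kinds of peak were simulated from the score group itself, so differences within a group were not tested.

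The alternatives tried were reciprocal overlap of 50%, peak centres within 100 bp, peaks resized to 200 bp, peaks at or above each list's median score, autosomes only, peaks beyond 1 kb of a TSS only, random placement on the chromosome, promoters of 500 bp and 5 kb, genes within 1 kb or 100 kb, peaks from 1 to 10 kb only, and other backgrounds. Motif searches were not run because no genome sequence was used here. Correlation of replicates, leaving out each replicate and a replicate block were not run because the lists hold no value per library.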

Results

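Chromatin from kidneys of C57BL/6 mice aged 2 to 3 months was immunoprecipitated and sequenced to map where estrogen-related receptor gamma (ERRγ, a nuclear receptor encoded by Esrrg) and hepatocyte nuclear factor 1 beta (HNF1β, a homeodomain transcription factor encoded by Hnf1b) sit on the genome, and where both share a site. The series held 2 ERRγ ChIP libraries, 2 HNF1β ChIP libraries, 1 library in which HNF1β chromatin was precipitated again with an ERRγ antibody (reChIP), 1 matching reChIP with IgG, and 3 input libraries. The files gave 8702 ERRγ peaks, 12773 HNF1β peaks and 1892 reChIP peaks on mm10, with 1 merged value per peak and none per library. The ERRγ libraries came from chromatin sets 1 and 2, and the HNF1β and reChIP libraries all came from set 3, so the factor and the chromatin set cannot be told apart in a comparison of the lists. Sequencing depth is not stated in the files. Peaks and genes are not biological replicates, and the p-values and intervals below cover counting error over peaks or genes, not the spread between mice. The peak score is the authors' own value and is used here only to rank or describe peaks within 1 list.

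ERRγ peaks lay near genes of mitochondrial energy metabolism. Of the nuclear genes for respiratory chain complex I, which oxidises NADH, 28 of 36 had an ERRγ peak within 10 kb of the transcription start site (TSS), against 16.0% of other protein-coding genes. The same held for 22 of 24 genes of complexes II to IV, 13 of 16 genes of complex V (the ATP synthase), 22 of 24 genes of the tricarboxylic acid (TCA) cycle and pyruvate entry, and 19 of 22 genes of glycolysis and gluconeogenesis. Fatty acid oxidation genes followed with 16 of 24, genes of mitochondrial dynamics, biogenesis and transport with 19 of 29, and mitochondrial ribosomal protein genes with 15 of 30. Several of these counts rested on peaks within 1 kb of a TSS: from 1 to 10 kb, the TCA cycle (10 members), fatty acid oxidation (6) and glycolysis (14) still passed, complex V (2) and the mitochondrial ribosome (5) did not, and complex I (2), complexes II to IV (1) and mitochondrial dynamics (2) had a share below that of other genes. Genes of the cytosolic ribosome (2 of 35) and the proteasome (4 of 31) passed in neither direction (Fisher's exact test, adjusted p = 0.222 and 1).

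The highest-scoring ERRγ peaks within 10 kb of a protein-coding gene belonged to Eno1 (enolase, a glycolytic enzyme), Cabcoco1, Clybl (a mitochondrial lyase), Med23 (a Mediator subunit), Esrra (the related receptor ERRα), Atp1b1 (the beta subunit of the sodium-potassium ATPase), Slc25a39 (a mitochondrial carrier), Aco2 (mitochondrial aconitase), Atp5b (the beta subunit of ATP synthase) and Rara (a retinoic acid receptor). The Eno1 peak, at chromosome 4, 150236494 to 150236714, ranked 3 of 8702 and was annotated to the promoter. The Esrra peak, at chromosome 19, 6922210 to 6922413, ranked 7 and was centred upstream of the TSS, at -503 bp. Among complex I genes the leading peaks were at Ndufa12, Ndufb5, Ndufs7 and Ndufb4, with ranks 78, 83, 84 and 121. Those of complexes II to IV were at Uqcr10 (rank 25), Uqcrc1 (rank 100), Cox5a (rank 110) and Cyc1 (rank 112). Complex V was led by Atp5b, Atp5g3, Atp5g2 and Atp5a1. The TCA cycle list was led by Aco2 (rank 10), Idh3a (rank 35), Ogdh (rank 43) and Pdk2 (rank 120), a kinase that restrains pyruvate entry. For glycolysis, Eno1 was followed by Aldoa (rank 14), Ldhb (rank 39) and Ldha (rank 65).

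Kidney tubule genes also lay near ERRγ peaks. They included 23 of 40 proximal tubule genes, 9 of 20 thick ascending limb genes, 11 of 24 distal convoluted and connecting tubule genes and 8 of 20 intercalated cell genes. Examples were Slc47a1 (an organic cation exporter), Slc9a3 (the apical sodium-proton exchanger), Umod (uromodulin), Atp1b1, Fxyd2 and Atp1a1 (the other sodium-potassium ATPase genes of the list), Car2 (carbonic anhydrase) and Atp6v0a4 (a proton pump subunit). Genes of monogenic tubulopathies (22 of 47, of which 41 are also in another list) and of ERR and HNF1 factors and their cofactors (13 of 24) lay near ERRγ peaks more often than other genes too. Markers of principal cells (6 of 19), podocytes (4 of 18), endothelium (1 of 20), fibroblasts and mesangium (1 of 20) and leukocytes (3 of 20) did not pass, nor did cystic disease and cilia genes (6 of 30). Neuronal synapse genes (3 of 22) and skeletal muscle genes (1 of 22), taken as tissues outside the kidney, did not pass either. Peaks were called on kidney chromatin and not per cell type, so sites bound only in scarce cell types may be missed. A list that did not pass is not shown to be unbound. In all, 14 of 24 lists passed an adjusted p of 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over 72 tests of 24 lists and 3 peak lists). By the exact test, the odds ratio was 18.3 (95% interval 8.14 to 46.6, adjusted p = 1.24e-14) for complex I and 3.47 (1.23 to 9.25, adjusted p = 0.0237) for intercalated cells. With the background limited to genes near a peak of any of the 3 lists, 5 of the 14 lists still passed: complex I, complexes II to IV, the TCA cycle, mitochondrial dynamics, and glycolysis.

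HNF1β peaks lay near genes of the proximal tubule, the segment that reabsorbs most filtered solutes. Of 40 proximal tubule genes, 35 had an HNF1β peak within 10 kb, against 13.4% of other genes (Fisher's exact odds ratio 45.3, 95% interval 17.7 to 148, adjusted p = 7.57e-24). The leading members were Ggt1 (gamma-glutamyltransferase), Slc34a1 (the sodium-phosphate cotransporter), Slc22a2 (an organic cation transporter) and Slc17a3, with ranks 15, 205, 768 and 806 of 12773. Distal convoluted and connecting tubule genes (13 of 24, led by Trpm7, Atp1b1, Fxyd2 and Kcnj16) and thick ascending limb genes (8 of 20, led by Cldn10, Ptger3, Ppp1r1a and Umod) passed as well. So did tubulopathy genes (20 of 47) and ERR and HNF1 factors (10 of 24), whose leading members were Hnf4a, Hnf1a, Hnf1b and Pcbd1, a dimerisation cofactor of HNF1 proteins.

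Some metabolic lists lay near HNF1β peaks too. TCA cycle genes did in 12 of 24 cases (led by Mpc2, Suclg2, Mdh1 and Fh1), fatty acid oxidation genes in 9 of 24 (led by Ehhadh, Acsm1, Acot2 and Acadl), and genes of glycolysis and gluconeogenesis in 9 of 22. The latter were led by G6pc (glucose-6-phosphatase, rank 16), Pck1 (phosphoenolpyruvate carboxykinase, rank 201), Ldhb and Pklr. Complex I (3 of 36), complexes II to IV (5 of 24), complex V (3 of 16), mitochondrial dynamics (5 of 29) and the mitochondrial ribosome (3 of 30) did not pass. The same was true of the cytosolic ribosome (4 of 35), proteasome (4 of 31), principal cells (1 of 19), intercalated cells (2 of 20), podocytes (4 of 18), endothelium (2 of 20), fibroblasts (1 of 20), leukocytes (2 of 20), synapse (0 of 22), muscle (1 of 22) and cystic disease genes (8 of 30). As for ERRγ, these lists are not shown to be unbound in scarce cell types. The highest-scoring HNF1β peaks near protein-coding genes were at Akr1c19, Adgrf1, Tmem207, Trhr, Ggt1, G6pc, Evc, Cyp2j5, Gm21992 and Cys1 (cystin, a ciliary protein). The Ggt1 peak lay at chromosome 10, 75566014 to 75566238, in sequence annotated as intergenic. In all, 8 of 24 lists passed, and with the background limited to genes near any of the 3 peak lists 1 list, that of the proximal tubule, still passed as more often and 3 passed as less often than other genes (complex I, complexes II to IV and the mitochondrial ribosome). That background holds only genes with a peak of some list, so a list rich in peaks of 1 factor has a lower relative share for the other by construction.

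**Figure D1:**
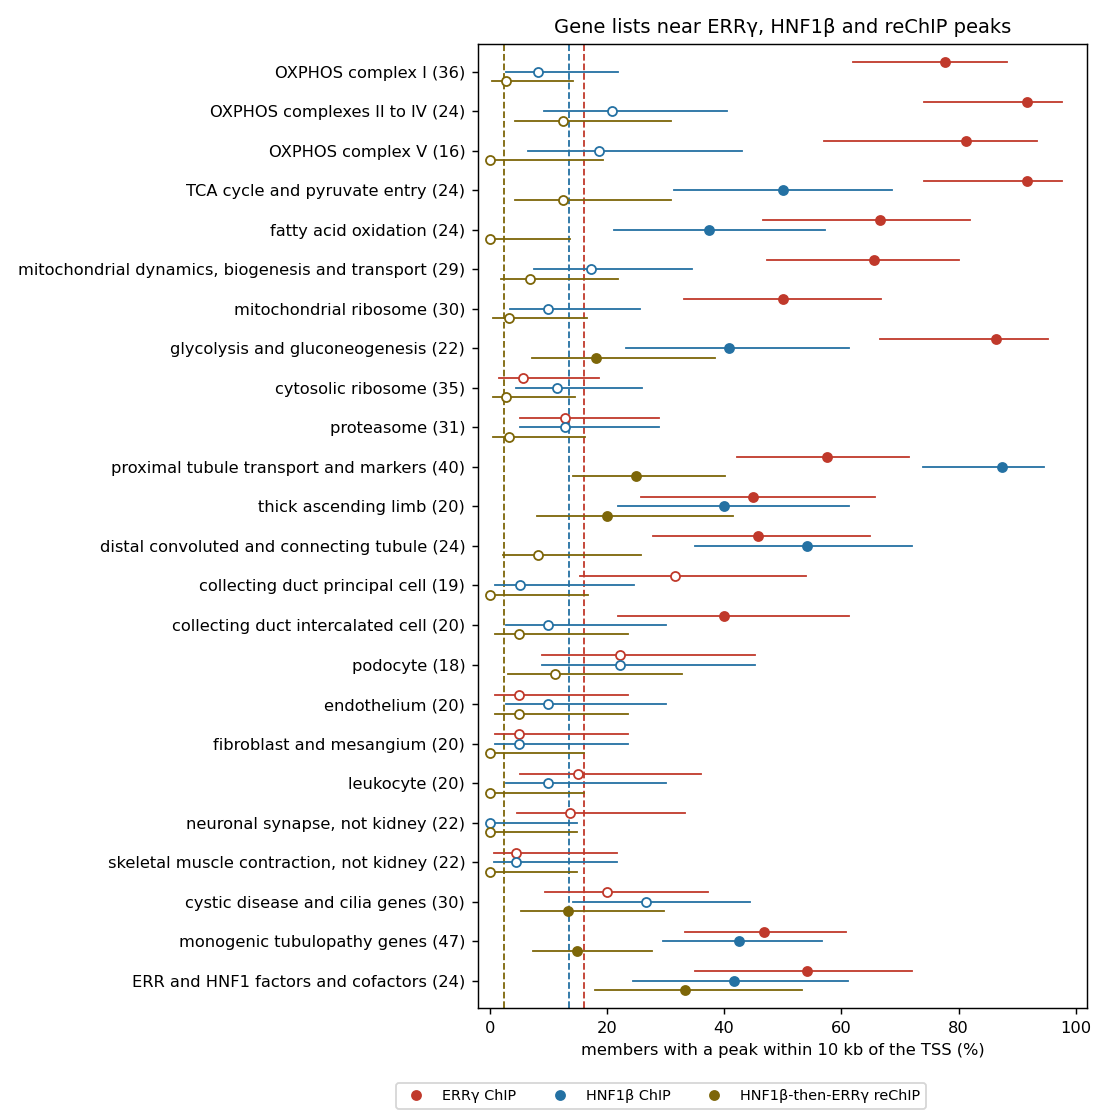
Share of each gene list's members (number in brackets) with a peak within 10 kb of the TSS, in percent, for ERRγ, HNF1β and reChIP peaks, with 95% Wilson intervals as horizontal lines. Filled points passed an adjusted p of 0.05, open points did not, and dashed lines mark the share among other protein-coding genes. ERRγ reached 22 of 24 genes of complexes II to IV, and HNF1β reached 35 of 40 proximal tubule genes.

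The factors' lists differed in which gene groups they reached alone and in how close to genes their peaks lay. For complex I, 25 genes had an ERRγ peak only and 0 an HNF1β peak only, and for complexes II to IV the numbers were 17 and 0. The split was 10 to 0 for the TCA cycle, 15 to 1 for mitochondrial dynamics and 13 to 1 for the mitochondrial ribosome. Proximal tubule genes split the other way, with 2 near ERRγ only, 14 near HNF1β only and 21 near both. Each of these 6 splits differed from that of all other protein-coding genes (Fisher's exact test, two-sided, adjusted p from 2.58e-05 to 0.0266 over 24 lists). An exact McNemar test within each list, which does not allow for the different numbers of peaks, passed for 8 lists, these 6 with complex V and glycolysis, each split 11 to 1 (adjusted p = 0.0502 by the Fisher test). Peaks centred within 1 kb of a TSS made up 27.8% (95% Wilson interval 26.9 to 28.8) of ERRγ peaks and 8.84% (8.36 to 9.34) of HNF1β peaks (odds ratio 3.97, 3.68 to 4.29). The median distance to the nearest TSS was 9336.5 bp for ERRγ and 25262 bp for HNF1β. With only peaks from 1 kb to 10 kb counted, 0 of the 24 splits passed (4 at an unadjusted p under 0.05). Fisher's exact test also no longer passed for the proximal tubule split within 100 kb (adjusted p = 0.274) and for the TCA cycle and mitochondrial ribosome splits within 1 kb (adjusted p = 0.113 and 0.130), each in the same direction.

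**Figure D2:**
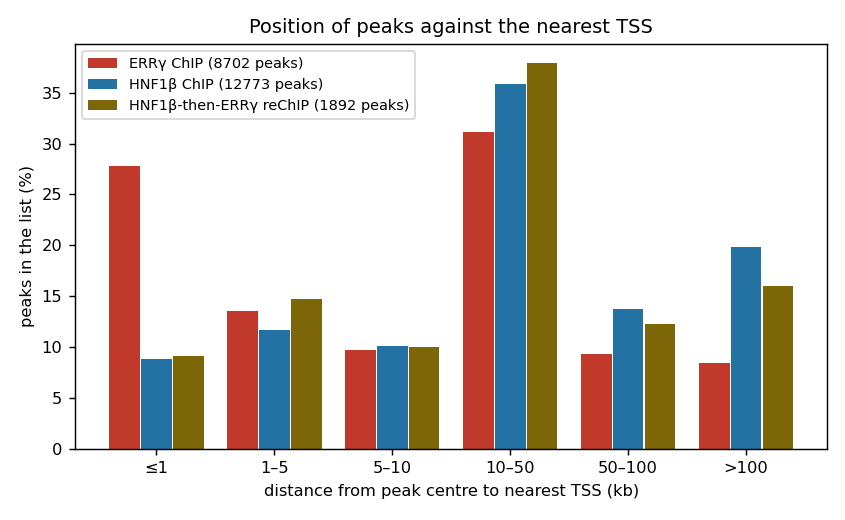
Share of peaks in each list, in percent, by distance from the peak centre to the nearest TSS in kb, for 8702 ERRγ, 12773 HNF1β and 1892 reChIP peaks. The bin up to 1 kb holds 27.8% of ERRγ peaks, 8.84% of HNF1β peaks and 9.14% of reChIP peaks.

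The genes of the factors themselves carried peaks. The Hnf1b promoter had an HNF1β peak at chromosome 11, 83852709 to 83852952, centred at -130 bp from the TSS with rank 180, and it overlapped a reChIP peak. An ERRγ peak that overlapped no HNF1β peak lay in exon 2 of 9 of Hnf1b, at chromosome 11, 83855877 to 83856237. Intron 1 of Esrrg held an ERRγ peak (rank 3629 of 8702) and, apart from it, a low-ranking HNF1β peak (rank 10438 of 12773). Hnf1a and Hnf4a, transcription factors of epithelial cells, had HNF1β peaks of rank 175 and 174, each overlapping a reChIP peak. ERRγ also had a peak within 10 kb of Hnf1a but none within 10 kb of Hnf4a. Ppargc1a, a coactivator of ERR receptors, had no peak within 10 kb in any of the 3 lists.

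A subset of ERRγ and HNF1β peaks overlapped, and these are called shared here. Overlap between separate libraries does not show that both factors sit on the same chromatin or in the same cells. Only the reChIP, described below, bears on that. The shared sites included the promoters of Slc17a1 (an anion transporter of the proximal tubule), Umod and Kcnj16, and sequence upstream of Atp1b1 and Ppp1r1a. Of these, the Kcnj16 peaks overlapped no reChIP peak. Of 8702 ERRγ peaks, 1210 (13.9%, 95% Wilson interval 13.2 to 14.6) overlapped an HNF1β peak by at least 1 bp, and 1210 of 12773 HNF1β peaks (9.47%, 8.98 to 9.99) overlapped an ERRγ peak. When each HNF1β peak was moved 20 to 200 kb along its chromosome, 1000 draws gave a mean of 39.8 overlapping ERRγ peaks (SD 6.36, highest 68), so the observed number was 30.4 times the mean (one-sided permutation p = 0.001, the smallest these draws can give). The Atp1b1 site lay at chromosome 1, 164460886 to 164461105 for ERRγ (rank 8) and 164460991 to 164461194 for HNF1β (rank 271), in intergenic sequence upstream of the gene, with the ERRγ peak centred at -2640 bp. The median distance between the centres of overlapping peaks was 76.8 bp.

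Shared peaks had higher scores than the rest of their list. The median score of shared ERRγ peaks was 19.0 against 15.4 for the others, a log2 difference of 0.30, and that of shared HNF1β peaks was 15.9 against 12.6, a log2 difference of 0.33 (two-sided permutation test, p = 1e-05 for both, the smallest that 100000 permutations can give). Shared ERRγ peaks lay at promoters less often than other ERRγ peaks (17.3% and 29.5%, odds ratio 0.499, Fisher's exact test, adjusted p = 1.05e-19), while shared HNF1β peaks did so more often than other HNF1β peaks (17.0% and 7.98%, odds ratio 2.37, adjusted p = 1.99e-21).

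The reChIP recovered sites near genes of the tubule and of the HNF1 network. HNF1β was precipitated first, and 1726 of 1892 reChIP peaks lay on HNF1β peaks, so these tests may repeat the HNF1β result. No test used only genes near HNF1β peaks as background, so the lists that passed do not show joint binding. Proximal tubule genes had a reChIP peak within 10 kb in 10 of 40 cases, against 2.49% of other genes (Fisher's exact odds ratio 13.1, 95% interval 5.67 to 27.6, adjusted p = 3.05e-07). They were led by Slc17a1, Miox (myo-inositol oxygenase), Slc7a9 (a cystine transporter subunit) and Slc13a1 (a sulfate transporter). ERR and HNF1 factors followed with 8 of 24 (odds ratio 19.5, 7.20 to 48.6), led by Pax2, Hnf1b, Hnf1a and Hnf4a. The leading reChIP peaks at Pax2, Hnf1b, Hnf1a and Hnf4a each overlapped an HNF1β peak and no ERRγ peak. Thick ascending limb genes passed with 4 of 20 (Ppp1r1a, Umod, Cldn10 and Tmem72), glycolysis and gluconeogenesis with 4 of 22 (Aldob, Pkm, Fbp1 and Aldoa), tubulopathy genes with 7 of 47, and cystic disease and cilia genes with 4 of 30 (Pkhd1, Umod, Ttc21b and Glis2). The Pkhd1 peak, at the promoter of the gene mutated in recessive polycystic kidney disease, lay at chromosome 1, 20618017 to 20618217, on an HNF1β peak.

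The remaining 18 lists did not pass for the reChIP. Complexes II to IV and the TCA cycle each had 3 of 24 members near a reChIP peak (Fisher's exact test, adjusted p = 0.0527 for both, and 0.0475 for both with all protein-coding genes as background, where they passed), the distal convoluted tubule 2 of 24, mitochondrial dynamics 2 of 29 and podocytes 2 of 18. Single members were near a reChIP peak for complex I, the mitochondrial ribosome, the cytosolic ribosome, the proteasome, intercalated cells and endothelium (1 each), and 0 members for complex V, fatty acid oxidation, principal cells, fibroblasts, leukocytes, synapse and muscle. Each peak counted only for its nearest gene, and this rule was not varied. Aco2 of the TCA cycle was thus not counted, although its ERRγ peak, centred at -262 bp, overlapped a reChIP peak. The TCA cycle result, close to the threshold, may turn on this rule. With the background limited to genes near any of the 3 peak lists, the proximal tubule list and the list of factors still passed. The highest-scoring reChIP peaks near protein-coding genes were at Neurl1b, Atp1b1, Fgfr4, Aoc1, Evc, Smad7, Zfp36l1, Plekha8, Slc17a1 and Cys1. Those that overlapped both an ERRγ and an HNF1β peak were led by Atp1b1, Evc, Smad7 (an inhibitor of TGF-beta signalling), Slc17a1, Ihh (a hedgehog ligand), Ablim1, Zkscan1, Sh3tc1, Nfic and Erbb2 (a receptor tyrosine kinase). The reChIP peak at Atp1b1, at chromosome 1, 164460977 to 164461177, ranked 8 of 1892, and that at Evc, in an intron at chromosome 5, 37331226 to 37331426, ranked 15.

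Most reChIP peaks lay on HNF1β peaks, and fewer on ERRγ peaks. Of 1892 reChIP peaks, 348 (18.4%, exact 95% interval 16.7 to 20.2) overlapped both an ERRγ and an HNF1β peak, among them those at Atp1b1, Slc17a1, Miox, Slc7a9, Ppp1r1a and Umod. A further 1378 (72.8%) overlapped an HNF1β peak only, as at Hnf1b, Hnf4a, Pkhd1 and Fxyd2, and 61 (3.22%) an ERRγ peak only, as at Esrra, Aldoa, Pdk2 and Sdhb. The other 105 (5.55%), with the peak at Plekha8 among them, overlapped neither. When reChIP peaks were moved 20 to 200 kb, 1000 draws gave a mean of 0.806 peaks on both (highest 5), 5.99 on an ERRγ peak and 8.25 on an HNF1β peak (one-sided permutation p = 0.001 for each, the smallest possible here). The reChIP began with HNF1β chromatin, so an excess on HNF1β peaks follows from the protocol. Since ERRγ and HNF1β peaks also overlapped more than moved peaks, these draws cannot tell whether both factors were bound together. Peaks within 1 kb of a TSS made up 9.14% of the reChIP list (7.93 to 10.5), with an odds ratio of 1.04 (0.878 to 1.23) against the HNF1β list. Within 5 kb the odds ratio was 1.21 (1.08 to 1.36). Of reChIP peaks on an ERRγ peak, 14.4% were at promoters, against 7.69% of the rest (odds ratio 2.02, Fisher's exact test, adjusted p = 8.92e-05).

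HNF1β peaks that carried an ERRγ peak had a reChIP peak more often than those that did not. The share was 29.1% (352 of 1210, 95% Wilson interval 26.6 to 31.7) with an ERRγ peak and 11.9% (1374 of 11563, 11.3 to 12.5) without (odds ratio 3.04, 2.65 to 3.49, Fisher's exact test, two-sided, p = 3.47e-51). The share also rose with the HNF1β peak score. In the lowest of 5 equal groups by HNF1β score it was 2.05% (3 of 146) with and 0.166% (4 of 2409) without an ERRγ peak. In the highest group it was 44.5% and 30.4%. Over the 5 score groups the combined odds ratio was 2.44 (2.11 to 2.83). It averages over groups that differed: the relative difference between the shares was largest at low scores and smallest at high scores. In the lowest group this difference rested on few reChIP peaks and is imprecise. The reChIP was a single library, so these shares have no replicate check.

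**Figure D3:**
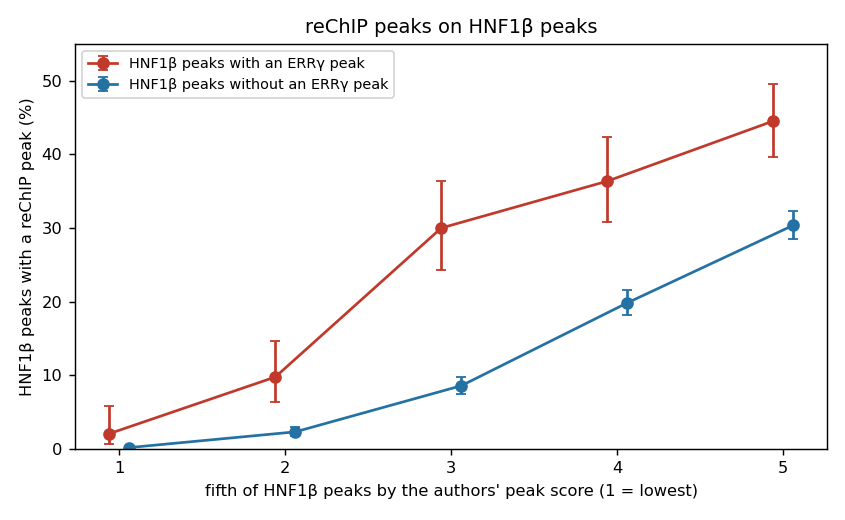
Share of HNF1β peaks with a reChIP peak, in percent, in 5 equal groups by the authors' HNF1β peak score, for HNF1β peaks with and without an ERRγ peak. Points are shares and bars are 95% Wilson intervals over peaks; in the highest group the shares were 44.5% and 30.4%.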

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

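Of the tests below, that of cytosolic ribosome and proteasome genes was chosen after the result was seen, and that of the OXPHOS promoter split after the numbers of OXPHOS genes near each factor were seen. For 6 gene lists the members near a peak of 1 factor only split between ERRγ and HNF1β differently from other genes, by Fisher's exact test of the split itself, which is what drew attention to them. Members near an ERRγ peak only numbered 25 for complex I, 17 for complexes II to IV, 10 for the TCA cycle and pyruvate entry, 15 for mitochondrial dynamics, biogenesis and transport and 13 for the mitochondrial ribosome, against 0, 0, 0, 1 and 1 near an HNF1β peak only. For the proximal tubule list, 14 members were near an HNF1β peak only and 2 near an ERRγ peak only.

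Among genes of these 5 mitochondrial lists near 1 factor only, nearly all lay near ERRγ, although the TCA cycle list as a whole also passed for HNF1β (12 of 24). A general preference of the ERRγ list for active promoters would place ribosome and proteasome genes near ERRγ peaks as well, but their odds ratio was 0.519, with a 95% interval that included 1 and lay wholly below that of OXPHOS genes (25.7, 14.0 to 50.9). A lack of HNF1β peaks at promoters of any kind would split OXPHOS promoters like other promoters, but 57 had an ERRγ peak only and 0 an HNF1β peak only, with a lower 95% bound of 5.61 for the odds ratio. For OXPHOS genes, these values argue against both explanations as the whole cause. Both tests were chosen after related counts were seen, and the promoter split rests largely on the peaks that form the pattern. Neither test is independent support for the pattern. A difference between chromatin sets was not tested and stays open, since set and factor coincide, beside binding of ERRγ itself at these genes.

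ERRγ and HNF1β peaks overlapped 30.4 times as often as local moves gave. With peaks within 1 kb of a TSS left out, the ratio was 38.2, which argues against shared promoters as the whole cause. Among the lowest-scoring 2555 HNF1β peaks, 146 overlapped an ERRγ peak (mean of draws 7.32, highest 22), so the excess was not confined to high-scoring HNF1β peaks. Regions recovered in any immunoprecipitation stay open, since the peaks were not grouped by ERRγ score or input signal. Open chromatin shared by both factors was not tested, because no accessibility data were used here, and may account for any part of the excess.

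Most reChIP peaks lay on HNF1β peaks without an ERRγ peak (1378 of 1892). Carry-over of HNF1β chromatin that depended only on HNF1β peak score would leave no relation to ERRγ among peaks of like score. The odds ratio over score groups was 2.44 (2.11 to 2.83), which argues against carry-over of that form as the whole cause. This ratio does not show joint binding. ERRγ chromatin that the HNF1β antibody had not selected, a candidate explanation given under the other observations, could raise it too and was not separated here. A carry-over that differs between peaks of like score was not tested, and the IgG reChIP had no values of its own here. Carry-over at part of the sites stays open. ReChIP and HNF1β scores went together across 1726 overlapping peaks (Spearman 0.675, across peaks). Since HNF1β was precipitated first, joint binding could give this correlation too, so it cannot decide. ERRγ sites too weak for the ERRγ list could explain another part: HNF1β peaks on the lowest-scoring ERRγ peaks had an odds ratio of 1.44 (0.931 to 2.22), against 3.91 (lower 95% bound 3.06) on the highest-scoring ones, so the ratio was higher at strong ERRγ peaks and the interval at weak ones, which includes 1, leaves this open. Joint binding of both factors at sites missed in the other chromatin sets was not tested.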

How the results depend on the processing

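Of the alternatives, lists without peaks shared by both factors (with reChIP peaks on HNF1β peaks only) and 50 score groups were chosen after the data were seen. The background of all protein-coding genes was the planned one, and became an alternative when the background was narrowed after the files were read. Of 70 alternative values for the main comparisons, 51 counted as unchanged: tests by direction and side of the threshold, shares by the 95% interval of the reported share, and numbers of lists by a ratio of at most 1.5. Overlap of ERRγ and HNF1β peaks was 30.4 to 51.7 times the mean of the draws in every setting run, and the odds ratio of a reChIP peak for HNF1β peaks with an ERRγ peak was 2.43 to 4.14. The 19 others follow, and for all but the changed definitions of overlap and promoter and the background of genes near a peak, whose construction sets the direction, the cause was not tested.

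The share of ERRγ peaks on an HNF1β peak was 9.78% at a reciprocal overlap of 50%, 8.79% with centres within 100 bp, 12.7% with peaks resized to 200 bp, 11.0% among peaks at or above the median score and 15.9% beyond 1 kb of a TSS. The share of reChIP peaks on both was 12.6% at a reciprocal overlap of 50% and 12.6% with centres within 100 bp. Promoter shares of ERRγ, HNF1β and reChIP peaks were 21.2%, 6.72% and 6.29% within 500 bp and 41.4%, 20.5% and 23.8% within 5 kb. At or above the median score, those of ERRγ and HNF1β were 28.9% and 7.45%. Between the reChIP and HNF1β lists, promoter shares passed a test only within 5 kb (odds ratio 1.21, Fisher's exact test, unadjusted p = 0.00107).

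With peaks from 1 to 10 kb only, 0 lists differed between the factors (4 at an unadjusted p under 0.05, and 0 by the exact McNemar test). Near ERRγ peaks, 2 members of complex I, 1 of complexes II to IV and 2 of mitochondrial dynamics remained, a share below that of other genes, and complexes II to IV had a difference of -2 between members near ERRγ only and near HNF1β only. The mitochondrial splits were thus not seen without peaks within 1 kb of a TSS. Splits also lost the call for the proximal tubule within 100 kb, the TCA cycle and mitochondrial ribosome within 1 kb, and the TCA cycle without shared peaks. With all protein-coding genes, the planned background before it was narrowed, complexes II to IV and the TCA cycle passed for the reChIP. With genes near any of the 3 peak lists as background, 5 lists passed as more often for ERRγ, 1 for HNF1β and 2 for the reChIP, and 3 passed as less often for HNF1β (complex I, complexes II to IV and the mitochondrial ribosome). That background keeps only genes that already have a peak, which lowers the relative share of 1 factor where the other is frequent, so the changes of direction it gave are no evidence of fewer peaks. The direction changed for the 23 proximal tubule genes near ERRγ peaks and, near HNF1β peaks, for 5 genes of complexes II to IV, 12 of the TCA cycle, 9 of fatty acid oxidation and 9 of glycolysis. Of 672 values of single lists, 601 were unchanged in direction and call, 47 lost the call, 15 gained it and 9 changed direction. Within 1 kb, 10 of the 14 ERRγ lists, 6 of the 8 HNF1β lists and 5 of the 6 reChIP lists kept their call. Within 100 kb the numbers were 13, 7 and 5, and from 1 to 10 kb they were 9, 6 and 4. At or above the median score they were 14, 7 and 4, and without shared peaks 13, 7 and 5.

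No paired analysis was possible because the files hold 1 value per merged peak and none per library, although the labels share replicate numbers 1 and 2. For the same reason replicates were not left out or correlated. Motif tests (no genome used here) and another height column (none in the files) were not run. Depth limits the lists: a site missing from the reChIP list, from 1 library, is not shown to be unbound.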

Other observations

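The test of reChIP peaks on ERRγ peaks without HNF1β, the scan of gene families and the comparison of the X chromosome were chosen after the data were seen. Among 65 gene families formed from symbols with at least 8 members (195 tests over the 3 peak lists, Fisher's exact test with Benjamini-Hochberg adjustment), families passed in both directions, and the examples below were picked after their values were seen. Solute carriers were not tested as 1 class, and many of their families did not pass. By this exact test, HNF1β peaks lay within 10 kb of 14 of 25 Slc22 genes (organic ion transporters, adjusted p = 1.32e-05), 8 of 16 Slc7 genes (amino acid transporters, adjusted p = 0.00592), 7 of 14 Slc16 genes (monocarboxylate transporters, adjusted p = 0.0112) and 8 of 21 Slc6 genes (adjusted p = 0.0299). By the same exact test, ERRγ peaks lay near 17 of 27 Cox genes (adjusted p = 1.16e-06), 14 of 23 Ndufa genes (adjusted p = 2.65e-05) and 9 of 12 Ndufb genes (adjusted p = 0.000164), which include assembly factors such as Cox10 and Ndufaf4 because families were formed by symbol prefix alone, and near 13 of 29 Mrps and 17 of 49 Mrpl genes. They also lay near 17 of 47 Slc25 genes, the mitochondrial carriers (exact test, adjusted p = 0.0101), 7 of 12 Slc2 genes, the hexose transporters (adjusted p = 0.0108), and 10 of 25 Slc22 genes (adjusted p = 0.0277). The reChIP had 4 of 21 Slc6 genes (Slc6a6, Slc6a13, Slc6a18 and Slc6a20b) and 4 of 25 Slc22 genes (Slc22a1, Slc22a8, Slc22a14 and Slc22a26). HNF1β also had 7 of 9 Ugt1 genes, but these overlap in 1 locus and are uncertain as separate genes.

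Olfactory receptor genes, silent in most tissues, lay near peaks less often than other genes: 1 of 1108 for ERRγ, 24 of 1108 for HNF1β and 0 of 1108 for the reChIP (adjusted p = 4.20e-83, 4.96e-40 and 1.47e-11, exact test). Genes with a symbol starting Krt, keratin-associated protein genes among them, were also near peaks less often, 0 of 112 for ERRγ and 3 of 112 for HNF1β (exact test, adjusted p = 1.64e-07 and 0.00187). All the family tests count each gene as independent. Genes of a family can be neighbours on a chromosome, which was not allowed for, so these p-values may be too small. On the X chromosome lay 79 of 8702 ERRγ peaks (0.908%) and 255 of 12773 HNF1β peaks (2.00%), an odds ratio of 0.450 (95% interval 0.349 to 0.580). The factors' libraries came from different chromatin sets, and the sex of the mice was not used here.

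A hypothesis set before its result was seen was that ERRγ peaks lie near subunit genes of the vacuolar proton pump. They did for 8 of 23 genes with a symbol starting Atp6v, among them Atp6v1b1, Atp6v0a4, Atp6v0b and Atp6v1d, at an odds ratio of 2.78 (95% interval 1.02 to 6.99, exact test). The lower bound is close to 1, the adjusted p among the 195 family tests was 0.109 (exact test), and 1 of the 8 genes, Atp6v1fnb, was counted by its symbol without a check that it encodes a subunit. The odds ratio without this gene was not computed, so the hypothesis about subunit genes stays undecided.

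Among ERRγ peaks without an HNF1β peak, 43 of 1393 in the highest-scoring group of 5 (3.09%) had a reChIP peak, against 19 of 6099 others (0.312%), an odds ratio of 10.2 (5.92 to 17.5). Of the 20 highest-scoring of these ERRγ peaks, 11 had one, as at Clybl, Med23, Esrra, Slc25a39 and Aco2. A candidate explanation is that the second antibody recovered some ERRγ chromatin that the HNF1β antibody had not selected. HNF1β binding at these sites below the calling limit would give the same pattern and was not tested.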
